A study of Mus musculus with 6 samples.

How the data were processed

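The series covers 6 libraries from LF2 mouse embryonic stem cells, 1 in each of 6 groups: tagged Prdm14 chromatin precipitation, the same double precipitation from untagged wildtype cells, H3K4me1 precipitation, input DNA, RNA after Prdm14 knockdown and RNA after a control knockdown. Per the labels' protocols, poly(A) RNA was selected with oligo-dT and copied with random hexamers, and no strand information is kept. The deposited files of the tagged and untagged precipitations give the start and end of each peak in mm9 and no score. The peak caller, its threshold and any control subtraction are not given in the sources used here. The 4 other deposited files hold 1 line per read, with its sequence and its matches in mm9 with up to 2 mismatches, so all read counts were made here from lines the authors deposited without counts of their own. The aligner is not given in the sources used here, and the form of the lines is that of ELAND output.

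Reads with a single best match were used. Input had 10578813 reads of 36 bases, of which 76.2% were uniquely placed, and H3K4me1 had 10831239 of 25 bases with 80.5%. The knockdown RNA library had 13506926 reads of 32 bases and the control 13181658, with 68.4% placed in each. Distinct start positions made up 91.5% of placed reads in input, 95.3% in H3K4me1 and 65.1% in each RNA library. Reads without molecular identifiers are not independent molecules, and 1 library per group gives no spread between replicates. Keeping 1 read per start position and strand removes copies but also caps the count of densely read genes. That cap can pull their ratios toward 1, so a smaller ratio in this setting does not tell copies from the cap. No p-value was computed across genes.

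No genome sequence or annotation of mm9 was used here, so genes were handled in 2 ways. Transcribed regions were built from the RNA reads of both libraries together, joining reads up to 1 kb apart, and 21323 regions with at least 50 reads in both libraries together were kept. They held 93.3% of placed knockdown reads and 93.7% of placed control reads, and their median length was 8885 bases. The joining distance was chosen after several had been compared and the calls had been viewed once. Named genes were located by sequence. The genome under the reads was rebuilt from read sequences and their mismatches, translated in all frames, and searched for windows of 10 residues of protein sequences. These protein sequences were written from memory after the data had been received, and they are not taken from a database. A gene was located with at least 5 matching windows in protein order, at least 2 times as many as at the next place, on the chromosome that the gene table of GRCm38 gives for its symbol, and in that table's order of located genes. GRCm38 starts served only for this order, and no position given here comes from GRCm38. The acceptance rule was written after the first raw matches had been seen, and the search was run 2 times.

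Of 222 sequences tried 197 were located, with a median of 100 windows and a lowest of 5. Of the 25 others, 17 had a second place too close, 4 lay on another chromosome than the table, 2 had too few windows and 2 were out of protein order. Reversed sequences gave 0 located of 222 and at most 1 window at a place. The sequence written for Zyx matched 59 windows on another chromosome and was refused, so recall can be wrong and a name rests on recall, the reads and the table together. Of the 222 sequences, 74 were written before any RNA difference had been seen and 148 after, some for list members whose regions had stood out, among them Lama1, Srgn, Spry4, Dusp6, Cldn6, Cdkn1c and Stra8. Of 332 symbols in the 16 lists 187 were tried and 163 located, so a list's value describes its located members only.

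A located gene was counted on its exon islands, stretches of RNA reads up to 50 bases apart that hold a match, so exons without a match are missing. No island held matches of more than 1 gene. Matches cannot always tell close paralogs apart, and Krt8, Krt18 and Krt19 are affected. Ratios are knockdown over control, scaled by a trimmed mean that leaves out 30% of ratios and 5% of abundances at each end, which multiplied the raw ratio by 0.991. Intervals of read ratios are exact conditional binomial intervals at 95%, and those of medians come from ranked values. A gene or region was called higher or lower with a ratio of 2-fold or more, an interval beyond 1.5-fold and at least 50 reads in both libraries together. Of the 197 located genes 48 were higher, 7 lower, 97 neither, and 45 had too few reads. Apart from Prdm14, 33 located genes were outside the lists and were chosen after values were seen, so these counts are not shares of all genes.

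List medians used a pseudocount of 0.5 and lists with at least 3 measured genes, and were placed as percentiles among 10000 random lists of regions, each member drawn from the 200 regions nearest in read number. List members were counted on islands and random members over regions, so the percentiles compare unlike stretches. The lists were pluripotency, extraembryonic endoderm, trophectoderm, post-implantation epiblast, primitive streak and mesoderm, neural ectoderm, germ cell, FGF-ERK, DNA methylation, PRC2 and Prdm14 cofactors, 2-cell-like, fibroblast or feeder, p53 and stress, interferon, cell cycle and housekeeping.

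The lists, thresholds, comparisons and most alternatives were fixed before the data were examined. The fixed rule for named genes took Prdm14 first, the 12 largest rises and 12 largest falls with at least 100 reads, passing members of the lists (at most 6 in each of the pluripotency, endoderm and trophectoderm lists and 3 in every other), and Gata6, Gata4, Sox17, Nanog, Pou5f1, Sox2, Klf4, Klf5, Esrrb, Fgfr1, Fgfr2, Dnmt3b and Tet1 whatever their values. Fgfr2 was not located. The largest changes were taken over regions whose starts lay at least 100 kb apart and named only where a located gene matched inside, so filters on gene class could not be applied. Peaks were named by nearness to a named gene, and not by score, since none is held. Not every peak within 50 kb of a named gene is given. Lamc1, Serpinh1, Hnf4a, Sparc, Krt19, Inhbb, Hspa1b, Aqp3 and the genes of the closing part on other observations were chosen after their values were seen.

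A Prdm14 peak counted as shared with 1 base of overlap. Distances ran from peak centres to transcribed regions in place of annotated starts, and were set beside 2404 random positions on the same chromosomes. The motif was counted on both strands within 100 bp of centres and in flanks 2 kb away, on rebuilt sequence, with Fisher's exact test across positions in place of the test across peaks first chosen, because coverage was incomplete. For sequences of 8 bases, the 4098 with at least 15 occurrences in centre windows were compared. H3K4me1 and input reads were shifted by 80 bp, counted within 1 kb and divided by the placed reads of their library. Random positions matched on distance to regions were at first drawn at input reads, which selects on the divisor. After that value had been seen they were redrawn uniformly in 10 kb bins with at least 1 input read.

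The procedures were tested on simulated data with counting noise only. Among 21323 simulated regions, 50 of 50 at 4-fold higher, 50 of 50 at 3-fold higher, 49 of 50 at 3-fold lower and 50 of 50 at 4-fold lower were called, and 0 unchanged ones. The changed regions were drawn from those with at least 100 reads, so recall between 50 and 100 reads was not tested. Of 100 unchanged lists 4 fell in the outer 5% of random lists, and 100 of 100 lists shifted 2-fold lay in the upper tail. The true H3K4me1 ratio lay in 193 of 200 intervals, and 100 of 100 planted motifs were found. Motifs were planted in complete random sequence, so that count says nothing about gaps in the rebuilt sequence. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Alternatives covered scaling, read minimum, fold, copies, coding stretches, reads with several places, region joining, windows, distances, control positions and the first 1202 peaks of the list.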

Results

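The series holds 6 libraries from LF2 cells, a mouse embryonic stem cell line of strain 129J grown without feeder cells, with 1 library in each of 6 groups. Prdm14, a PR-domain zinc finger protein of pluripotent and germ cells, was tagged with FLAG and HA and precipitated through both tags, and untagged cells were precipitated the same way as a control. For these 2 libraries the files give peak positions without heights. Input DNA and an H3K4me1 precipitation, a histone mark found around enhancers, came as aligned reads, with 8057636 and 8722902 reads placed at a single best position. Poly(A) RNA of a Prdm14 knockdown and of a control knockdown gave 9238111 and 9019522 such reads. No group has a replicate, so each comparison sets 2 libraries side by side and cannot separate the condition from the library. Coordinates are those of mm9. Intervals are 95% intervals. Those of read ratios cover counting error only. Those of list medians reflect the spread over genes, those of shares the number of peaks, regions or bins, and those of chromosomes the spread over bins.

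To ask where tagged Prdm14 bound, the peaks of the tagged cells were set beside those of untagged cells. The tagged library had 2404 peaks with a median width of 820 bp, and the untagged library had 45. None of the Prdm14 peaks overlapped a peak of the untagged cells. Upper limits of 0.153% (exact binomial interval) and 0.125% (a floor of 3 peaks) reflect the number of peaks only. They do not cover the single untagged library or the peak calling. The 45 untagged peaks spanned 57.8 kb in all, and the overlap to be had by position alone was not computed. Per 10 Mb, Prdm14 peaks were densest on chromosome 11, at 16.6, followed by chromosomes 8 at 12.75, 19 at 12.4 and 17 at 12.3. A peak at chromosome 1, 13117881 to 13119044, lay 1.98 kb from the matched exon of Prdm14 itself. Peaks also lay 1.58 kb from the matched exons of Pou5f1 and 1.85 kb from those of Sox2, both core pluripotency transcription factors. Of other pluripotency factors, Klf5 had its nearest peak at 26.1 kb, Nanog at 51.0 kb, Klf4 at 52.1 kb and Esrrb at 304 kb. A peak within 50 kb was common, at 42.3% of the 97 located genes whose RNA passed neither way. The peaks named here are therefore examples and show no preference for such genes. The nearest peak to Gata4, a regulator of endoderm, was 4.36 kb away, and that of Dnmt3b, a de novo DNA methyltransferase, was 18.0 kb away. A peak at chromosome 10, 77510818 to 77512898, overlapped the matched exons of Dnmt3l, a cofactor of de novo methylation. These distances run to matched coding stretches, not to annotated starts. Whether the authors subtracted a control before calling peaks is not given in the sources used here, and subtraction would lower the overlap.

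Prdm14 peaks lay in or beside transcribed regions more often than random positions did. Of the 2404 peak centres, 36.3% (34.4 to 38.3) were inside a transcribed region or within 1 kb of it, against 13.2% (11.9 to 14.7) of random positions on the same chromosomes. At the other end, 12.5% of peaks and 48.6% of random positions were over 100 kb from any transcribed region. Exons, introns and promoters were not told apart, because no annotation of mm9 was used here.

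The sequence under the peaks was read to ask which motif marks bound sites. The motif GGTCTCTAA, the sequence reported for Prdm14 in the field, occurred at 28 of 221697 readable positions within 100 bp of peak centres and at 2 of 301420 positions 2 kb away (odds ratio 19.04, two-sided Fisher's exact test across positions, p = 5.52e-09). With flanks at 500 bp, which held 7 occurrences, the odds ratio was 7.09, and with 1 mismatch allowed it was 4.90. Of the 4098 sequences of 8 bases compared, GTCTCTAA ranked first, with 69 occurrences at centres and 13 in flanks (Bonferroni p = 2.72e-11, one-sided Fisher's exact test). GGTCTCTA, also part of the motif, was the third in rank, with 56 against 11. GCCACACC, which shares no long stretch with the motif, was found 63 times at centres and 19 times in flanks (Bonferroni p = 8.53e-07, Fisher's exact test). In all, 28 of the 4098 sequences passed the correction. Reads covered 56.3% of centre bases and 39.2% of flank bases, so 28 of 2327 readable peak windows with the full motif is a minimum, and positions of 1 peak are not independent.

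H3K4me1 was higher relative to input around Prdm14 peaks than at positions 50 kb to either side. Within 1 kb of the centres the ratio of H3K4me1 to input, each scaled to its library's reads, was 1.93 (1.91 to 1.96), against 1.37 (1.36 to 1.39) at the distant positions, and the medians per position were 1.89 and 0.994. A ratio above 2 was found at 44.7% of peaks and 18.5% of distant positions. The ratio was 1.87 at peaks inside transcribed regions or within 1 kb, 2.02 at 1 to 10 kb, 2.02 at 10 to 100 kb and 1.78 beyond 100 kb. At the centre itself it was 1.25 (1.22 to 1.29), below the 1.41 of the distant positions there, and it was 2.22 at 1000 bp on the downstream side of the map. At the 45 peaks of untagged cells the pooled ratio was 0.332 (0.326 to 0.337), and with 1 read per start position it was 0.931. The median per position there was 0.815, with all reads. Input was itself denser at Prdm14 peaks, with a median of 20 reads per window against 10 at the distant positions, and the ratio divides by this. H3K4me1 reads had 25 bases and input reads 36, so unique placement can differ between them by position. The ratios were not corrected for this.

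**Figure D1:**
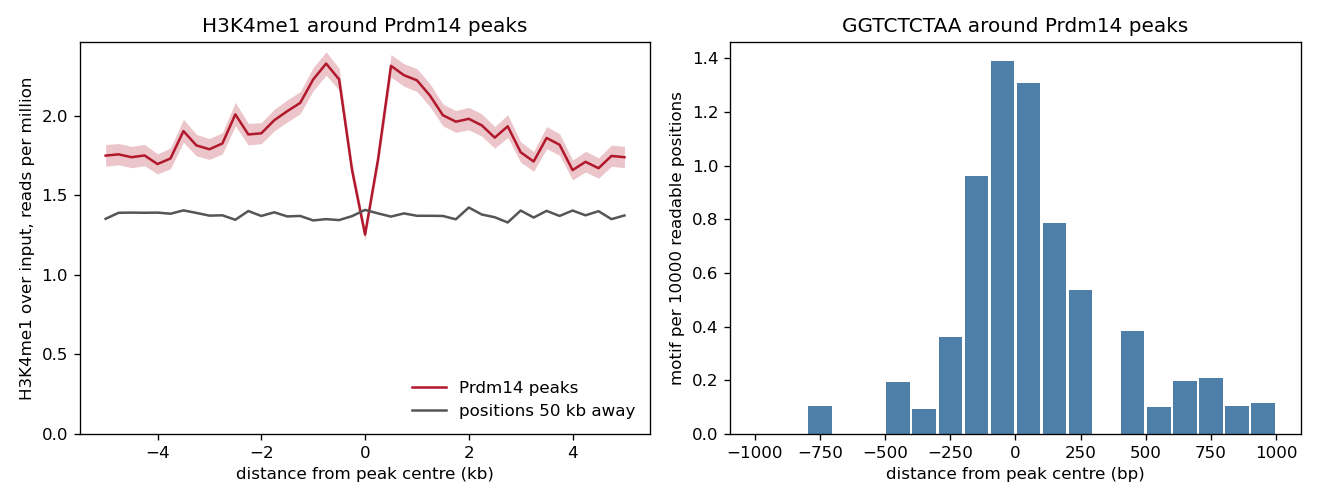
Left, the ratio of H3K4me1 to input, each scaled to its library's reads, by distance from the peak centre in kb, for 2404 Prdm14 peaks (red, shading the 95% counting interval) and positions 50 kb away (grey). Right, occurrences of GGTCTCTAA per 10000 readable positions by distance from the centre in bp. The ratio is 1.25 at the centre with higher shoulders, and the motif is densest at the centre.

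A check of the H3K4me1 label was tried at the borders of transcribed regions, grouped by their reads in the control knockdown library. In the quartile of regions with the densest reads the ratio to input was 0.975 (0.965 to 0.985) within 1 kb of the borders and 1.12 (1.11 to 1.12) at 1 to 5 kb. In the quartile with the sparsest reads the values were 1.29 (1.27 to 1.30) and 1.31 (1.30 to 1.32). With 1 read per start position the value of 0.975 in the densest quartile became 1.19, above 1. The quartiles from sparsest to densest then stood at 1.27, 1.17, 1.21 and 1.19 within 1 kb, so most of the contrast was lost. Without strand information these borders also mix starts and ends of transcripts. The label could therefore not be checked this way.

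The knockdown was first checked on its target. On the exon-like stretch that could be assigned to Prdm14, chromosome 1, 13115524 to 13115904, the knockdown library held 54 reads and the control library 120, a scaled ratio of 0.446 (0.317 to 0.620). Prdm14 thus passed the rule for a fall, with a counting interval below 1. Over the joined transcribed region holding that stretch the ratio was 0.802. With 1 read per start position it was 0.4997 and on the matched coding stretch alone 0.413, and none of these 3 values passed the rule. Each value lay on the side that the label names, and the size of the fall depended on the stretch counted.

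Genes of the extraembryonic endoderm, the lineage lining the yolk sac, were higher in the Prdm14 knockdown library. Of 18 measured members of this list, 15 rose, none fell, and 3 did not pass, with a median log2 ratio of 2.48, at percentile 100 among 10000 random lists. The basement membrane collagens Col4a1 and Col4a2 rose 15.8-fold (13.6 to 18.6) and 13.0-fold (10.6 to 16.2). The transcription factor Sox7 rose 10.8-fold (5.46 to 24.3), the endocytic adaptor Dab2 10.3-fold (6.95 to 15.7), the keratin Krt8 9.53-fold (6.75 to 13.8) and the proteoglycan Srgn 8.96-fold (5.87 to 14.3). Gata6 and Gata4, transcription factors that drive this lineage, rose 7.80-fold (4.54 to 14.4) and 4.96-fold (3.84 to 6.47). Sox17 had 24 reads in the knockdown and 0 in the control library, a ratio with a counting interval from 5.97 upward, but stayed under the minimum of 50 reads. Members that did not pass were Lamc1 at 1.57-fold, Serpinh1 at 1.26-fold and Hnf4a at 0.910-fold. Keeping 1 read per start position caps densely read genes, so a smaller ratio there does not by itself show copies. With 1 read per start position Col4a1 stood at 7.59-fold, Col4a2 at 8.39-fold and Krt8 at 5.97-fold, still passing. Sparc, 1 of the 15, then stood at 1.504-fold and did not pass. Krt19, another of them, stood at 3.06-fold, at 1.52-fold over its joined region, where it did not pass, and at 6.94-fold with distant matches left out, so its size is uncertain. Reads of Krt8 may be shared with related keratins. Among fibroblast markers, collagen I, decorin, matrix Gla protein and Thy1 together had 25 and 22 reads, a ratio of 1.13 (0.609 to 2.10), and the only measured marker, Tagln, rose 5.43-fold on its exons but stood at 1.19 over its joined region.

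Pluripotency factors kept their RNA within the 2-fold rule. None of 21 measured members passed it, and the list median was -0.09 on the log2 scale, at percentile 1.15 among random lists. Pou5f1 stood at 0.975-fold (0.939 to 1.01), Nanog at 0.744 (0.709 to 0.780), Sox2 at 0.694 (0.663 to 0.726), Klf4 at 0.748 (0.692 to 0.809) and Esrrb at 0.754 (0.724 to 0.786), while Klf5 stood at 1.39 (1.30 to 1.49). None of 5 measured trophectoderm genes passed, with a median of 0.34 at percentile 98.8. Gata3 stood at 2.05 (1.31 to 3.25), while Tfap2c at 0.575 and Ets2 at 0.813 went the other way. Under the read minimum, Hand1 had 20 reads against 4 and Ascl2 21 against 5, with intervals above 1. Cdx2 had 3 against 1. With so few measured genes, a rise in this list is neither shown nor excluded.

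**Figure D2:**
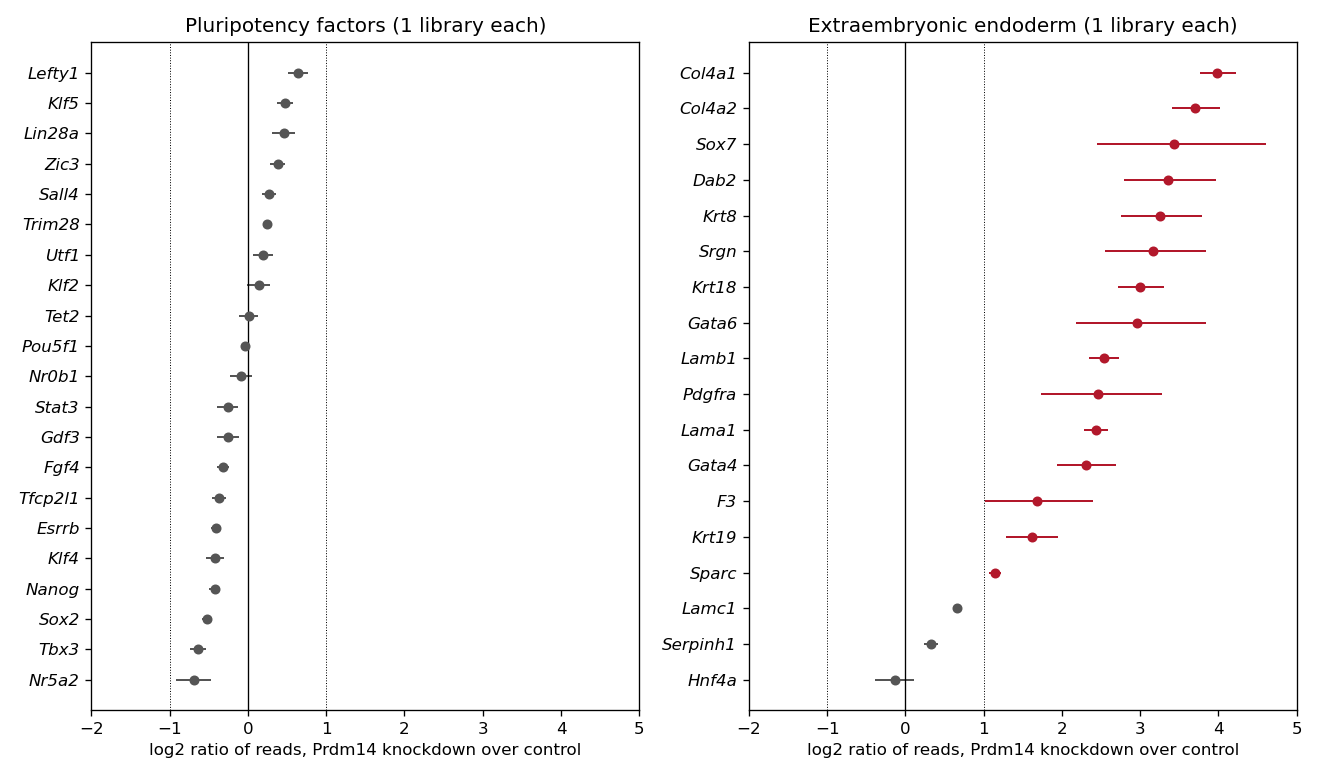
Ratio of scaled reads, Prdm14 knockdown over control, on a log2 axis, for each measured member of the pluripotency list (left) and the extraembryonic endoderm list (right), 1 library each. Points are genes, bars exact 95% counting intervals, red points pass the rule for a rise, and dotted lines mark 2-fold. In the endoderm list 15 of 18 genes rose, and none of the 21 pluripotency factors passed.

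Other lists moved less or rest on fewer genes. Of 8 post-implantation epiblast genes 3 rose, with a median log2 ratio of 0.28 at percentile 99.5. They were Cldn6, a tight junction protein, at 5.90-fold on exons but 1.78-fold over its joined region, the cadherin Cdh2 at 3.03-fold and Dnmt3b at 2.49-fold (2.29 to 2.72). Of 10 DNA methylation enzymes, Dnmt3b and Dnmt3l rose, Dnmt3l by 2.08-fold (1.98 to 2.19). With 1 read per start position Dnmt3l stood at 1.51-fold and no longer passed. Dnmt3l is densely read, with 4357 and 2074 reads, so this does not tell copies from the cap of that setting. Tet1, an enzyme that oxidises methylcytosine, stood at 0.963. The median of that list was 0.04, at percentile 73.1. Of 10 FGF-ERK genes, the feedback inhibitors Dusp4 and Spry4 rose 3.23-fold and 2.53-fold, and the median was 0.80 at percentile 100, with the receptor Fgfr1 at 1.10-fold. Of 6 germ cell genes, Stra8, which is needed for entry into meiosis, fell to 0.127-fold (0.0745 to 0.206), and the median was -0.89 at percentile 0. Only 1 of the measured FGF-ERK genes and 0 of the germ cell genes were located before RNA differences had been seen, so these 2 shifts are not independent of the data. The same holds for the p53, cell cycle and PRC2 lists, with 0 such genes each, and in part for epiblast with 3 of 8, neural with 1 of 3, DNA methylation with 4 of 10 and housekeeping with 2 of 9. Of 3 neural genes Sox11 rose 3.96-fold and Pax6 fell to 0.341-fold, or 0.687 over its joined region, where it did not pass, with a median of 0.20 at percentile 76.1.

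The remaining lists were described in the same way. Of 9 p53 and stress genes Atf3 rose 2.81-fold, with a median of 0.18 at percentile 99.3. Of 14 cell cycle genes Cdkn1c, an inhibitor of cyclin-dependent kinases, rose 6.81-fold and Ccnd2 2.61-fold, with a median of -0.07 at percentile 9.57. None of 5 PRC2 and Prdm14 cofactors passed, with a median of 0.03 at percentile 65.0. None of 9 housekeeping genes passed either, yet their median of 0.15 lay at percentile 98.3, so a percentile of that height was also reached by a list with no stated link to Prdm14. With 1 read per start position, which also caps densely read genes, the housekeeping median was 0.01. Snai1 rose 4.27-fold and Bst2 2.05-fold, but the mesoderm and interferon lists had 2 measured genes each and got no median. Some calls failed the rule on fewer reads with ratios of similar size or larger: Atf3 at 3.15-fold and Snai1 at 5.35-fold on coding stretches, and Sox11 at 3.66-fold and Ccnd2 at 2.45-fold with 1 read per start position. Bst2 stood at 1.72-fold with 1 read per start position. No gene of the 2-cell-like list was located.

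Across the 21323 transcribed regions, 332 were higher and 101 lower in the knockdown library by the rule, with 127 of the higher and 10 of the lower at 4-fold or more. Of the 12 largest rises 7 were in located genes, and beyond the lists these included Thbs1, a secreted matrix glycoprotein, whose region stood at 11.9-fold (6.25 to 25.4). The largest rise, 16.4-fold (8.41 to 36.6), was in a region with no assigned gene at chromosome 8, 11311327 to 11313765, with 149 reads against 9. It lay between the matched stretches of Col4a1 and Col4a2, so it may be an unmatched part of either gene. Another such region at chromosome 7, 149761436 to 149764024, had 4963 reads against 427, a ratio of 11.5 (10.4 to 12.8). Among the largest falls were Stra8 and Tgm2, a transglutaminase, whose region stood at 0.294 (0.242 to 0.356). A region with no assigned gene at chromosome 1, 74426009 to 74433121, had 23 reads against 98, and one at chromosome 4, 140505143 to 140508978, had 39 against 153. A region can hold part of a gene or several genes, so these are not counts of genes.

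Binding and RNA were then set side by side. Of the 101 regions lower in the knockdown library, 30.7% (21.9 to 40.7) had a Prdm14 peak within 50 kb, against 18.4% (14.4 to 22.97) of the 332 higher and 18.7% (18.1 to 19.2) of 20890 unchanged regions. Within 10 kb the shares were 12.9% (7.04 to 21), 7.53% (4.93 to 10.9) and 6.78% (6.44 to 7.13), and these intervals overlapped. Of located genes, 20 of 48 higher, 4 of 7 lower and 41 of 97 that passed neither way had a peak within 50 kb of their matched stretches, a tally added after the data were seen. Only 28 of these 48 and 2 of these 7 were members of the fixed lists, against 90 of the 97. Prdm14 was the target, and the other genes outside the lists were chosen after values were seen. The tally therefore does not weigh binding against change. Krt19, whose matches span neighbouring genes, is counted among the higher. The 4 lower genes were Prdm14, Pax6, Inhbb and Hspa1b, the last of which may share reads with a paralog, while Stra8, Tgm2 and Aqp3 had no peak within 100 kb. Among genes that rose, Gata4 and Dnmt3b had a peak within 20 kb, while Gata6 and Sox7 had none within 100 kb. The 1454 regions within 10 kb of a peak had a median log2 ratio of 0.02, at percentile 99.1, and 25 were higher and 13 lower. Within 50 kb that median was -0.01, at percentile 23.3. Over the nearest region to each peak, at any distance, it was 0.02, at percentile 99.9. With chromosome 8 left out the median within 10 kb was 0.01, at percentile 94.9, inside the range of random lists.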

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

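Of 662 alternative values, 581 stayed within the limit for their kind, 23 values of single genes no longer passed the rule, 57 moved further and 1 reversed. Single genes had to keep their direction and side of the threshold. Counts of regions and of shared peaks had to stay within 1.5-fold of the main value. Most other values had to stay inside the interval of the main value, which for list medians is the spread over genes. Of the 581, 109 equalled the reported value, some because the setting could not move it (0 shared peaks to leave out, or no list member on chromosome 8), and those say nothing about stability. The causes were not tested except where stated. All 111 list medians moved less than their wide intervals: pluripotency ran from -0.17 to -0.08 and extraembryonic endoderm from 2.27 to 2.66, but trophectoderm from 0.17 to 0.64, epiblast from 0.20 to 0.80, neural from 0.18 to 0.61, p53 from 0.05 to 0.18 and housekeeping from 0.01 to 0.15. Prdm14 is counted by its interval here, though it lost its call in 3 settings. Of 55 genes called, Prdm14 included, 54 were kept under scaling by total, 55 under the median of ratios and the upper quartile, 45 with 1 read per start, 47 on coding stretches, and none turned. Chosen after seeing the data were joined regions (48 of 55 kept), matches over 20 kb apart left out (55 kept), other joining distances, at least 20 windows, sequences written before RNA differences were seen, chromosome 8 left out, and the first 1202 peaks. Over its joined region Prdm14 stood at 0.802, a stretch that adds reads outside the matched exon. Higher and lower regions numbered 867 and 225 with no minimum beyond 1 read, 112 and 43 with at least 200, 1173 and 799 at 1.5-fold with an interval beyond 1, and 201 and 29 at 3-fold, as these looser or stricter rules must change a count. With reads up to 5 kb apart joined 47 were lower. Shares of regions near a peak moved with the distance by construction: within 2 kb 4.22%, 9.90% and 4.10% of higher, lower and unchanged, within 50 kb 18.4%, 30.7% and 18.7% of higher, lower and unchanged. By the nearest region to each peak they were 15.4%, 21.8% and 9.21%, and with the first 1202 peaks 3.92%, 5.94% and 3.79%. With the 1.5-fold rule 8.10% of higher, 9.51% of lower and 6.63% of unchanged regions had a peak within 10 kb. The median near peaks was -0.0075 within 50 kb. Peaks within 5 kb of a region made up 45.7%, and within 1 kb 38.4% of the first 1202. For H3K4me1 over input, values for the 4 distance classes follow from nearest to farthest. Windows of 500 bp gave 1.67 at peaks, 0.400 at untagged peaks and 1.58, 1.77, 1.77 and 1.51 by class. Windows of 2.5 kb gave 1.97 and 0.366, and 2.01, 1.98 and 1.70 in the nearest and the 2 farthest classes. Reads counted at their start gave 0.390 at untagged peaks. With 1 read per start the values were 1.90 at peaks, 0.931 at untagged peaks and 1.83 in the nearest class. Scaling by 10 kb bins gave 2.79 at peaks, 1.98 at control positions, 0.478 at untagged peaks and 2.71, 2.92, 2.91 and 2.56 by class. Control positions stood at 1.48 when 20 kb away and 1.18 when random and matched on distance. The first 1202 peaks gave 1.40 at control positions and 1.78, 2.07 and 1.93 in the nearest and the 2 farthest classes. By expression with 1 read per start, the sparsest quartile stood at 1.27 within 1 kb, and the 4 quartiles at 1.30, 1.19, 1.25 and 1.25 at 1 to 5 kb. The densest quartile within 1 kb reversed from 0.975 to 1.19. Not run were coding exons for regions, bases shared by 2 genes left out, starts of protein-coding genes, and the higher-scoring peaks, since no mm9 annotation and no score were held. No paired analysis was possible because each condition has 1 library. Depth limits genes such as Sox17, with 24 reads in all.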

Other observations

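The tests on fibroblast reads and on the share of cells were chosen only after the results they weigh had been seen, and the patterns themselves were noticed in the data. The bounds of the other tests were set before their values were seen, though after the RNA differences had been viewed. Genes outside the lists, also chosen after their values were seen, included the helix-loop-helix inhibitors Id1, Id2 and Id3, which rose 2.59-fold (2.13 to 3.16), 3.46-fold (2.52 to 4.82) and 7.03-fold (3.72 to 14.65). Id3 had a Prdm14 peak 2.32 kb away. Peg10, an imprinted gene of the placenta, rose 4.02-fold (3.80 to 4.26), or 2.06-fold with 1 read per start position, which caps densely read genes. Ccn1, a secreted matrix protein, rose 3.99-fold (3.29 to 4.86) with a peak 1.55 kb away. Aqp3, a water channel, fell to 0.376-fold (0.316 to 0.446), and Inhbb, a subunit of activin, fell to 0.416-fold (0.346 to 0.498). The untagged control peak at chromosome 2, 98502255 to 98503261, held 23133 input reads.

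Extraembryonic endoderm genes, from Col4a1 to Gata6, were higher in the knockdown library, which may come from loss of Prdm14 or from the single culture and library of each condition. With 1 read per start position the list median was 2.27 (1.32 to 2.70) on the log2 scale, above 1, which argues against copies of the same fragments as the whole cause. Collagen I, decorin, matrix Gla protein and Thy1 had knockdown reads of 0.216% (0.140 to 0.318) of the summed rise of the 15 endoderm genes, where the bound for fibroblasts was 10%. Of these 5 genes 4 had no transcribed region within 20 kb. Both values argue against fibroblast reads, as far as these 5 genes go. This bound and verdict replaced an undecided one after the values were seen. The percentage compares unlike coverage, since Col1a1 was matched over 31 windows and Col4a1 over 164. Tagln, the only measured fibroblast marker, was not in the sum. It rose 5.43-fold, with 115 and 21 reads, but did not pass over its joined region. The pluripotency median of -0.087 (-0.41 to 0.24) lay above the -0.51 set for a loss of the stem cell state in 30% of cells. That bound takes such cells to hold none of this RNA and as much RNA in all, which was not tested. The share cannot be excluded, a verdict also changed after the values were seen. The intervals of Sox2 and Klf4, 2 of 5 core factors, reach a share of 0.7. Outside these 5, Tbx3 at 0.642 (0.596 to 0.692) lay below 0.7, and the interval of Nr5a2, at 0.618 (0.528 to 0.722), reached it. The lower limits of the remaining measured members lay above 0.7.

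Input reads on chromosome 8 were 1.23 (0.977 to 1.37) times those of the autosomes, an interval that includes 1, so an excess is itself not established, while chromosomes 5, 7 and 11 stood at 1.199, 1.13 and 1.28, with intervals above 1. Against autosomal bins of the same base composition, chromosome 8 bins stood at 1.085 (1.02 to 1.31), an interval that spans the bound set for the test. Of its 104 bins 57.7% (47.6 to 67.3) lay above the median of the other autosomes, where an extra copy was set to give at least 80% and its absence under 60%. Base composition and an extra copy cannot be told apart here, because the first interval spans its bound and the second, though below 80%, reaches past 60%. With chromosome 8 left out, the endoderm median was 2.43 and 305 regions were higher.

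Regions lower in the knockdown library had a Prdm14 peak within 50 kb more often than unchanged regions. Lower regions had fewer regions within 100 kb, a median of 5 against 6, so region density already pointed the other way, and unchanged regions matched on it and on reads had a peak in 16.7%, below the 21.9 to 40.7% of lower regions. Distances ran from the whole region and region length was not matched, so a part played by length stays open. Higher regions were not compared with matched ones, and regions of 1 gene are not independent. Within 50 kb the share of higher regions was close to that of unchanged ones, but its interval overlapped that of lower regions, and with the 1.5-fold rule 9.51% of lower, 8.10% of higher and 6.63% of unchanged regions had a peak within 10 kb, so specificity to falls is not shown. By the nearest region to each peak higher regions also exceeded unchanged ones, at 15.4% against 9.21%, a measure not matched on neighbours, of which higher regions have a median of 4. No biological explanation was tested, the pattern was found and tested on the same data, and an effect of the single libraries stays open.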
